A study of Mus musculus with 8 samples.

How the data were processed

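RNA from 8 libraries of sorted mouse spleen CD8+ T cells was compared. According to the protocol text, spleens of adult or neonatal mice were processed, CD8+ cells were enriched on magnetic beads, and naive subsets were sorted by flow cytometry after staining for CD8, CD4, CD44, CD122 and viability. Which age each library came from is not given in the sources used here. RNA was extracted with Trizol, and libraries were prepared with a strand-preserving kit (Ultra II Directional, NEB). The sample titles divide the libraries into 4 groups of 2, by genotype label (WT or mCre) and subset label (TN or MP). The series title names miR-29 together with Cre, and the design text calls the subsets TN and VM; neither spells out which allele the mCre animals carried.

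The deposited table holds raw counts, whole numbers of reads per gene symbol and library. Per the submitters' processing notes, the tools were Trim Galore, HISAT2 and featureCounts and the genome build was mm10; versions and the gene annotation are not given in the sources used here. Neither are the strand setting and the treatment of reads that match several places. Reads from overlapping genes on opposite strands, and from near-identical paralogs, could therefore have been counted for either gene, and such genes are named as uncertain where they appear. The table had 29426 gene symbols and 0 lines that named no gene. Total counts per library ranged from 13479586 to 30057658.

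Differences were tested on the deposited counts with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with trimmed-mean (TMM) scaling, robust dispersion estimation and edgeR's expression filter, which kept 12313 genes. All 8 libraries entered a single fit with a mean for each of the 4 groups, so that the groups shared their estimate of the spread. The contrasts were MP against TN within each genotype, mCre against WT within each subset, and the difference between those differences (the interaction). An additive model with subset as covariate set the 4 mCre libraries against the 4 WT libraries. Tests were two-sided, p-values were adjusted with the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05 with no fold threshold. Positive log2 fold changes mean higher in MP or higher in mCre. Levels are counts scaled to library size (CPM), and log2 CPM used a prior count of 2.

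There were 32 gene lists, fixed together with the comparisons, the tests, the naming rule and the alternatives before the data were examined. For each list, members called higher or lower were counted, once with adjustment over all genes and once adjusted over the list alone. Lists with at least 5 tested members were tested with camera in limma 3.58.1, which compares a list with all other genes, at a preset correlation between genes of 0.01 and with Benjamini-Hochberg adjustment over the lists of a comparison. Camera with a correlation estimated from the data, which is less powerful with so few libraries, and fry, which asks whether a list's genes move on balance one way, were run beside it. The genes named for each comparison were the 8 with the largest positive and the 8 with the largest negative log2 fold change among called genes whose libraries did not overlap between the arms and whose mean log2 CPM was at least 3; for the interaction there were 5 per direction. Some genes that were measured are not reported here. Unnamed transcripts, pseudogenes and antigen receptor segments were not eligible. Up to 4 members with the smallest p were added per list, together with the sort markers and the miR-29 loci. Genes outside this rule are named as chosen after their values were seen.

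For the microRNA test, each gene's log2 fold change was regressed on the presence of a 7-base sequence (7mer) in its longest annotated 3' UTR, with log UTR length and UTR GC content as covariates, in numpy 2.4.6 under Python 3.11.15. The sequence pairing to miR-29 positions 2 to 8 was ranked among all 7mers present in at least 100 genes, and UTRs under 30 bases were not used. The sites of 13 other microRNAs were treated likewise. A site was called above the 97.5 percentile or below the 2.5 percentile. UTRs and coordinates came from GENCODE M21 on GRCm38, the assembly also called mm10; all 12313 tested symbols were found in it. Coordinates are 1-based.

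Where a group had a count of 0, the limit is 3 counts over the group, and confidence levels are 95%. Such limits and intervals cover counting error and nothing else, since reads without molecular identifiers are not independent molecules. P-values measure the spread between 2 libraries per group, and the labels do not state that these came from separate animals, so that spread may be technical.

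The procedure was tested on counts simulated from each gene's mean over all 8 libraries and the real library sizes, in a single draw per comparison. Apart from the genes changed for the comparison tested, the simulated groups did not differ, whereas the real groups differ in many genes. The shares rest on 49 or 50 genes changed 2-fold and on 9 to 18 unchanged genes called per comparison. They need not apply to the real calls. Of the genes changed 2-fold, 77.6% were recovered for genotype in TN (12089 genes tested) and 87.8% for genotype in MP (12089). The share was 90% for subset in WT (12094), 79.6% for subset in mCre (12102), 92% for genotype across subsets (12096) and 74% for the interaction (12100). Unchanged genes made up more of the calls than the nominal share in several of these simulations: 10.9% for genotype in TN, 11.2% for genotype in MP, 9.94% for subset in WT, 9.68% for subset in mCre, 10.6% for the interaction and 5.03% for genotype across subsets. A simulated 1.3-fold rise of the 38 tested interferon genes across subsets was called by camera, and 0 other lists were. Genes and libraries were drawn independently of each other in these simulations. They therefore do not show how often camera calls lists of correlated genes, or how TN and MP libraries of a single animal would affect the calls.

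Alternatives were relative log expression scaling, total counts without a composition factor, DESeq2 1.42.0, limma-voom, no expression filter, a stricter filter (1 CPM in 4 libraries), fits restricted to the groups compared, the replicate number as a block, and leaving out each library in turn. For the microRNA test, other site definitions, the shortest UTR and a model without covariates were also run. When a removal left a group with a single library, that library was assumed to vary like those of the other groups.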

Results

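Messenger RNA was measured in 8 libraries of CD8+ T cells sorted from mouse spleen, in 4 groups of 2 libraries each: WT-TN, WT-MP, mCre-TN and mCre-MP. TN and MP are subset labels, and the sort used CD44 and CD122, the surface proteins that set memory-phenotype CD8+ T cells apart from other naive cells. Total counts were 13479586 and 18585716 in WT-TN, 23386348 and 21877937 in WT-MP, 30057658 and 19304257 in mCre-TN, and 18351092 and 24566129 in mCre-MP. Between 14834 and 15722 genes were detected per library. The 10 most abundant genes took 5.26% to 5.5% of the counts, mitochondrial genes 2.17% to 2.52% and ribosomal protein genes 8.41% to 10%. Replicates differed by more than sampling noise in each group (chi-square per degree of freedom 4.6 in WT-TN, 6.12 in WT-MP, 5.9 in mCre-TN and 4.13 in mCre-MP). The correlation of log2 CPM between the 2 libraries of a group, across genes, which are not independent replicates, lay between 0.9905 and 0.9935. The first principal component held 71.6% of the variance and the second 10.8%.

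The genes of the sort markers followed the subset labels. Cd44 (chromosome 2, 102811141 to 102901665, minus strand) was at 14.79 ± 0.803 CPM in WT-TN and 141.9 ± 4.89 CPM in WT-MP (SD, n = 2 each), and at 14.62 ± 2.32 in mCre-TN and 157.8 ± 7.86 in mCre-MP. Il2rb, which encodes CD122 (chromosome 15, 78479256 to 78495271, minus strand), was at 195.2 ± 13.1 and 1352 ± 49.8 CPM in WT and at 186.7 ± 6.38 and 1231 ± 202 CPM in mCre. Cd8a lay between 1590 and 1808 CPM and Cd8b1 between 1303 and 1346 CPM in the group means. Cd4 had 3, 7, 6 and 10 counts in WT-TN, WT-MP, mCre-TN and mCre-MP. Of the 4 tested sort markers, 0 were called between mCre and WT in TN, in MP or across subsets by edgeR, DESeq2 or voom. At an unadjusted p under 0.05, 1 was higher in MP and 0 differed in TN or across subsets.

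**Figure D1:**
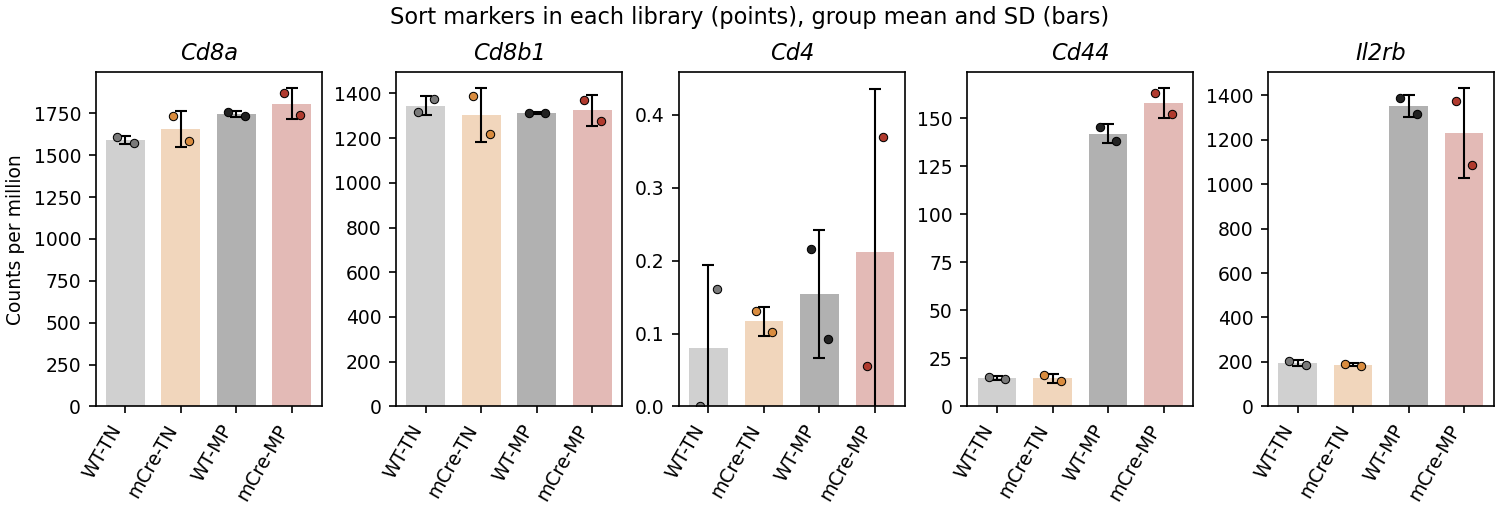
CPM (vertical axes, each from 0) of 5 sort marker genes in the 4 groups. Points are libraries, bars are means of 2 libraries and error bars are SD, with the lower end drawn no lower than 0; Cd44 and Il2rb are higher in both MP groups, and Cd4 stays under 1 CPM in each library.

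The series title names miR-29, a microRNA family encoded at a pair of loci. Precursor genes with a line in the count table were therefore examined in each group. Mir29b-1 had no such line and could not be examined. Mir29a (GRCm38 chromosome 6, 31062660 to 31062747, minus strand) had 0 counts in WT-TN, 1 in WT-MP, 0 in mCre-TN and 2 in mCre-MP. Mir29b-2 (chromosome 1, 195037040 to 195037120) and Mir29c (chromosome 1, 195037547 to 195037634) had 0 counts in each library, which allows up to 0.0936 CPM in WT-TN, 0.0663 in WT-MP, 0.0608 in mCre-TN and 0.0699 in mCre-MP. These precursor counts are too low to show a difference between genotypes at this depth, and mature microRNAs were not analysed here.

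MP cells of WT mice expressed effector chemokines, NK-type receptors and memory-associated genes that TN cells expressed at low levels, and had lower levels of several naive T cell genes. Ccl5, a chemokine stored by memory and cytotoxic lymphocytes (chromosome 11, 83525778 to 83530518, minus strand), rose from 3.23 ± 0.6 to 912 ± 23 CPM (SD, n = 2 each; log2 fold change 8.11, SE 0.0849, adjusted p = 2.4e-22). Cd163l1, a scavenger receptor family gene, rose from 5.78 ± 2.2 to 1160 ± 50 CPM (7.69, SE 0.282). Ccr9, a homing receptor for the gut (chromosome 9, 123678439 to 123784330, where other annotated genes overlap it), fell by 5.39 on the log2 scale (SE 0.491, adjusted p = 0.00197), from 111 ± 4.6 to 2.64 ± 0.35 CPM. Itgae, the integrin chain CD103, fell by 4.40 (SE 0.452), from 185 ± 3.1 to 8.73 ± 0.84 CPM. With edgeR, 3908 of 12313 genes were called, 1993 higher and 1915 lower in MP, of which 637 and 362 changed more than 2-fold.

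Other strong increases in WT-MP were those of Samd3 (log2 fold change 7.28), the kinase substrate Plek (6.05), Lrrk1 (5.96), the calcium-binding S100a6 (5.91), the receptor Slamf7 (5.42) and the protease inhibitor Ctla2a (5.11). Decreases included Ifngr2, a chain of the interferon gamma receptor (−4.10, SE 0.179), Ampd1 (−3.64), Igfbp4 (−3.50), Xkrx (−3.47), Ramp1 (−3.39) and Mtss1 (−3.14). Of 30 memory-phenotype markers, 25 rose, 1 fell and 4 did not pass the test (26 and 1 adjusted over the list alone), with a median of 2.504 (camera adjusted p = 6.67e-128). Of 19 cytotoxic effectors and cytokines, 17 rose and 1 fell (18 and 1 adjusted over the list alone; median 3.39, adjusted p = 5.26e-40). Gzmm (3.81) and Ifng (6.05, from 15 counts over both TN libraries) were among them. Xcl1 had 3 counts in WT-TN, a ratio of 304 with a counting interval of 104 to 1480, and Fasl had 1, a ratio of 538 with an interval of 96.4 to 21300. Of 20 NK-type receptors, 19 rose (19 adjusted over the list alone; adjusted p = 2e-33). Klrk1 rose from 10.6 ± 2.1 to 185 ± 8.5 CPM (4.14), and Klrc2 rose by 7.18. The median of this list was 7.17, or 4.68 when the 5 members without a count in WT-TN were set to the bound that a count of 0 allows. Klra7, a member of a family of near-identical genes whose reads may have been shared, had 2 counts in WT-TN, a ratio of 238 with an interval of 65.8 to 1970. Chemokine receptors and homing genes moved both ways (15 higher and 8 lower of 24, 15 and 8 adjusted over the list alone; median 0.49, adjusted p = 5.13e-23). Ccr2 (6.72), Cxcr3 (3.96), Cxcr5 (3.72) and Itgb1 (2.02) rose. These 4 list calls were kept with an estimated correlation (adjusted p = 0.00193, 0.0118, 0.0126 and 0.00543).

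Naive T cell genes moved mostly down in WT-MP, with 22 lower and 6 higher of 30 (22 and 6 adjusted over the list alone; median −0.33, camera adjusted p = 1.08e-05). The adjusted p was 0.0632 with an estimated correlation. Sox4 (−3.56), Actn1 (−0.86) and Rapgef4 (−0.85) fell, whereas Myb (1.93), the survival receptor gene Il7r (0.88) and Nsg2 (0.61) rose. Among 29 T cell transcription factors, 13 rose and 7 fell (13 and 8 adjusted over the list alone; median 0.17, adjusted p = 1.32e-05, adjusted p = 0.0632 with an estimated correlation). Bhlhe40 (4.86), Tbx21 (4.13) and Hopx (2.57) rose and Tox (−0.87) fell. Of 26 cytokine receptors, 17 rose and 7 fell (17 and 8 adjusted over the list alone; median 0.77, adjusted p = 2.06e-06, adjusted p = 0.0632 with an estimated correlation). Il18r1 (1.94) and Ifngr1 (1.17) rose and Il6st (−1.40) fell. Cholesterol synthesis genes fell in 14 of 25 cases and rose in 0 (15 and 0 adjusted over the list alone; median −0.30, adjusted p = 2.36e-06, adjusted p = 0.148 with an estimated correlation). Sqle (−1.95) was among them. Of 20 apoptosis regulators, 7 rose and 2 fell (7 and 3 adjusted over the list alone; median 0.19, adjusted p = 0.00194, adjusted p = 0.141 with an estimated correlation). Bcl2 (1.07) and Bcl2l1 (1.94), which protect cells from apoptosis, rose. Markers of NK cells and innate lymphoid cells, some of which are shared with the lists above, rose in 9 of 11 cases and fell in 1 (median 1.39, adjusted p = 2.63e-07, adjusted p = 0.0632 with an estimated correlation).

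Lists that camera did not call in WT included the interferon response (11 higher and 2 lower of 38, adjusted p = 0.0844), cell cycle genes (9 and 3 of 38, 0.181) and glycolysis (10 and 3 of 21, 0.206). The same held for heat shock and unfolded protein genes (12 and 0 of 21, 0.0755) and T cell receptor signalling (8 and 11 of 30, 0.209). Nor did it call DNA methylation genes (3 and 7 of 18, 0.0844), the microRNA pathway (1 and 6 of 14, 0.149), mitochondrially encoded genes (5 and 0 of 8, 0.0844) and ribosomal proteins (28 and 4 of 83, 0.127). Without the expression filter 6 of these lists passed: interferon (0.00117), cell cycle (0.0026), glycolysis (0.00443), heat shock (7.84e-05), mitochondrial (0.000435) and ribosomal (2.62e-05). Several passed once a single library was left out. The interferon list reached 0.00281 without mCre-MP replicate 1, 0.00258 without mCre-MP replicate 2 and 0.0264 without WT-TN replicate 2. Without WT-TN replicate 2 the ribosomal (0.00145), DNA methylation (0.0214) and heat shock lists (0.0281) passed as well. Without WT-MP replicate 1 the heat shock (0.0459) and mitochondrial lists (0.0278) passed, and without WT-MP replicate 2 the cell cycle list did (0.0472). For immediate-early genes, 10 higher and 4 lower of 27, the median (0.06) and the mean (−0.02) differed in sign (0.708). For the co-inhibitory receptors, 6 and 4 of 13, the median was 0.327 while the test pointed down (0.708). Fetal and neonatal lymphocyte genes had a median of −0.27 with 2 higher of 5 and an upward test (0.579). Markers of B cells, myeloid cells and dendritic cells stayed mostly without a call. B cell markers had 1 of 9 called (Cd22, 5.03, 6 against 281 counts; list median −0.12 with an upward test, 0.664), and myeloid markers 1 of 16 (Fcgr3, 1.39; 0.871). Dendritic cell markers had 3 of 13, all higher (Itgax, 4.65; 0.0844, but 0.0343 with the stricter filter). CD4 and regulatory T cell markers had 3 higher and 6 lower of 10 (0.574), and gamma-delta T cell markers 2 and 2 of 5 (0.206, but 0.00175 without mCre-TN replicate 1 and 9.2e-05 without mCre-TN replicate 2). Of 7 erythroid and platelet markers, 0 were called by edgeR, DESeq2 or voom, and 1 was lower at an unadjusted p under 0.05.

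In mCre mice the same comparison gave 4000 genes, 2092 higher and 1908 lower in MP, of which 637 and 345 changed more than 2-fold. Ccl5 rose from 4.61 ± 0.14 to 825 ± 19 CPM (SD, n = 2 each; log2 fold change 7.48, SE 0.0777, adjusted p = 2.1e-22). Plek (5.77), Cd163l1 (5.37), Slamf7 (5.28), Ctla2a (5.04), S100a6 (4.74) and Ly6c2 (4.64) rose too. Ccr9 fell by 4.30 (SE 0.404, adjusted p = 0.00214), from 153 ± 22 to 7.39 ± 5.6 CPM. Itgae (−3.69), Ifngr2 (−3.21), Ramp1 (−3.07), Ampd1 (−3.05), Xkrx (−2.80), Plekho1 (−2.58) and Igfbp4 (−2.52) fell. With a fit of the 2 mCre groups alone, Itgae and Igfbp4 did not pass the test (adjusted p = 0.0524 and 0.0601).

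Memory-phenotype markers in mCre counted 24 higher and 1 lower of 30 (25 and 1 adjusted over the list alone; median 2.89, camera adjusted p = 2.38e-133). Cytotoxic effectors counted 18 and 1 of 19 (18 and 1; median 2.82, adjusted p = 2.97e-44) and NK-type receptors 19 and 0 of 20 (19 and 0; adjusted p = 8.1e-24). For chemokine receptors and homing genes the numbers were 15 and 8 of 24 (median 0.46, adjusted p = 1.85e-26). With an estimated correlation these 4 lists' adjusted p-values were 0.0015, 0.016, 0.0302 and 0.00406. Tbx21 rose by 3.70, Ccr2 by 7.61 and Klrk1 by 3.89 on the log2 scale. The NK-type receptor median was 5.17, or 3.62 with the 6 members at 0 in one group set to their bound. Naive T cell genes counted 21 lower and 5 higher of 30 (median −0.40, adjusted p = 0.000138, adjusted p = 0.0609 with an estimated correlation). Transcription factors counted 11 higher and 10 lower of 29 (median 0.04, adjusted p = 0.00014, adjusted p = 0.0609 with an estimated correlation). Cytokine receptors counted 14 and 7 of 26 (median 0.65, adjusted p = 1.15e-06, adjusted p = 0.0684 with an estimated correlation). Cholesterol synthesis genes counted 14 lower and 0 higher of 25 (median −0.34, adjusted p = 1.66e-06, adjusted p = 0.128 with an estimated correlation). Apoptosis regulators counted 10 higher and 1 lower of 20 (median 0.21, adjusted p = 0.000299, adjusted p = 0.127 with an estimated correlation). NK and innate lymphoid markers counted 10 and 1 of 11 (median 1.55, adjusted p = 1.15e-06, adjusted p = 0.0684 with an estimated correlation).

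Interferon response genes (15 higher and 1 lower of 38, median 0.29, adjusted p = 0.00799) and glycolysis genes (13 and 2 of 21, median 0.33, adjusted p = 0.0249) passed camera in mCre. So did heat shock and unfolded protein genes (13 and 0 of 21, median 0.26, adjusted p = 0.0151), dendritic cell markers (3 and 0 of 13, median 0.20, adjusted p = 0.045) and ribosomal proteins (47 and 2 of 83, median 0.15, adjusted p = 0.0105). Their adjusted p-values with an estimated correlation were 0.586, 0.212, 0.37, 0.212 and 0.746. Without mCre-MP replicate 2 the last 4 did not pass (0.0522, 0.0805, 0.105 and 0.117), and the dendritic list did not pass without WT-TN replicate 1 (0.0509) or replicate 2 (0.0536), or with the replicate number as a block (0.051). Cell cycle genes counted 15 higher and 2 lower of 38 (adjusted p = 0.0736, but 0.0412 without WT-MP replicate 1 and 0.0372 without WT-MP replicate 2). DNA methylation genes counted 2 and 8 of 18 (0.0538, but 0.049 with total counts only), and this list also passed without mCre-TN replicate 1. Without the expression filter the transcription factor (0.172) and dendritic lists (0.112) did not pass, while the cell cycle (0.000239), DNA methylation (0.025), microRNA pathway (0.0244) and co-inhibitory receptor lists (0.0475) did. Gamma-delta markers, 2 higher and 2 lower of 5, had a median of −0.30 and an upward test (0.747, but 0.0228 without mCre-TN replicate 2).

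The subset differences of WT and mCre, which share no library, were close to each other. Among genes called in both, 1528 were higher and 1417 lower in MP in both genotypes, where independent lists would share 338.6 and 296.7, and 4 were called in opposite directions. Across the 12313 genes, which are not independent replicates, the log2 fold changes correlated with r = 0.878.

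**Figure D2:**
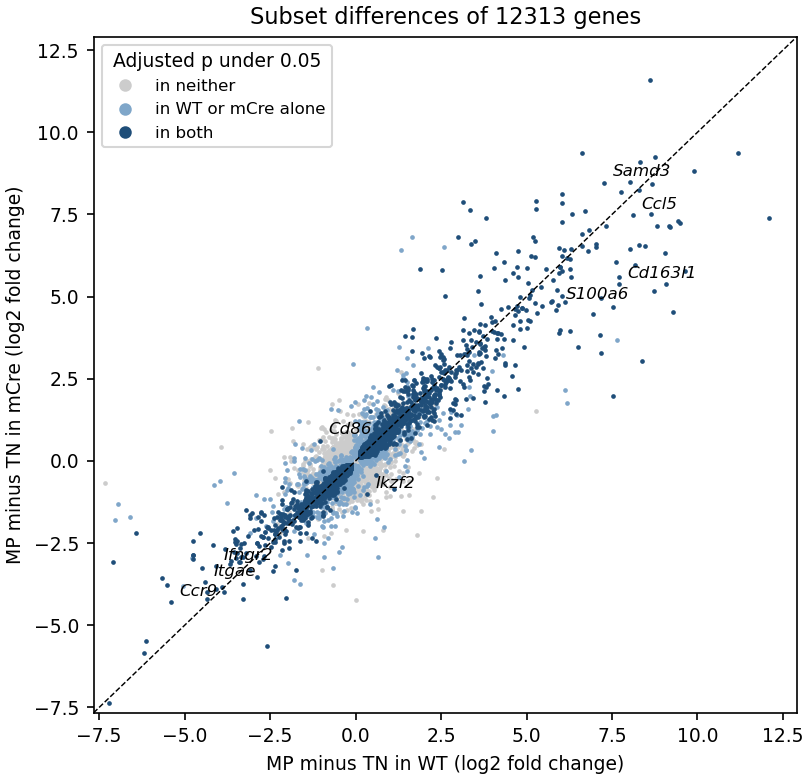
Log2 fold change of MP against TN in WT (horizontal axis) and in mCre (vertical axis) for 12313 genes, each point a gene estimated from 2 libraries per group. Dark points are the genes called in both genotypes, most of them near the dashed line of equal change; Ikzf2 and Cd86 are labelled as genes whose subset difference differed between the genotypes.

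In TN cells, mCre and WT differed in 427 genes, 191 higher and 236 lower in mCre, with 30 and 40 of them changed more than 2-fold. The GABA transporter gene Slc6a13 (chromosome 6, 121300227 to 121337733, plus strand) rose from 661 ± 32 CPM in WT to 1670 ± 71 CPM in mCre (SD, n = 2 each; log2 fold change 1.34, SE 0.0507, adjusted p = 2.35e-12). Ptk2b, which encodes the tyrosine kinase PYK2 (chromosome 14, 66153257 to 66281052, minus strand), fell by 1.41 (SE 0.0561, adjusted p = 3.55e-12), from 845 ± 76 to 318 ± 0.93 CPM. Als2cl (chromosome 9, 110879870 to 110900530, plus strand) fell by 1.67 (SE 0.108), from 189 ± 19 to 59.1 ± 2.1 CPM, with the reservation that Tmie overlaps it on the opposite strand. Fam135b rose from 7.09 ± 0.83 to 21.9 ± 3.9 CPM (log2 fold change 1.61, SE 0.149, adjusted p = 2.79e-06). The interferon-induced genes Rtp4 (1.15), Cmpk2 (1.13) and Usp18 (1.01, from 101 ± 5.3 to 201 ± 13 CPM) rose, although the calls of Cmpk2 and Usp18 were lost with some libraries left out.

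Arrdc3 (1.119), Agrn (1.05) and Dcaf17 (0.99, overlapping Mettl8) also rose in mCre-TN, and Ntrk3 (−1.01), H2-Q6 (−0.95), Acpp (−0.90), Rab20 (−0.84), the signalling adaptor Traf1 (−0.79) and the costimulatory ligand Cd86 (−0.79) fell. H2-Q6 has close paralogs, and its reads may have been shared with them. Of 38 interferon response genes, 13 rose and 1 (Epsti1, −0.23) fell (29 and 1 adjusted over the list alone; median 0.69, camera adjusted p = 2.93e-35). The adjusted p was 0.378 with an estimated correlation. Zbp1 (0.77), Trim30a (0.38) and Samd9l (0.35) were among those that rose. Of 16 myeloid markers, 4 fell (6 adjusted over the list alone; median −1.01, adjusted p = 4.48e-05, adjusted p = 0.737 with an estimated correlation): the complement gene C1qa (−1.58), Csf1r (−1.45), Hmox1 (−1.33) and Vcam1 (−1.25). Ribosomal protein genes fell slightly, 21 of 83 (58 adjusted over the list alone; median −0.15, adjusted p = 5.63e-17, adjusted p = 0.779 with an estimated correlation). Of 5 gamma-delta markers, 0 were called by edgeR and 1 by DESeq2 and by voom. At an unadjusted p under 0.05, 3 were higher and 1 lower (3 and 1 adjusted over the list alone). Their median was 0.62 and their mean −0.02 (camera adjusted p = 0.0123, adjusted p = 0.488 with an estimated correlation). Of 20 NK-type receptors, 0 were called by edgeR, DESeq2 or voom, and 1 was higher and 3 lower at an unadjusted p under 0.05 (camera adjusted p = 0.691). Without the expression filter the transcription factor (0.0293), glycolysis (0.0293) and erythroid lists (0.0351) passed. So did the DNA methylation list without WT-TN replicate 1 (0.0284), the erythroid list without mCre-TN replicate 1 (0.0258) and the glycolysis list without mCre-TN replicate 2 (0.0473).

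Fewer genes were called in TN without mCre-TN replicate 2 (204) or WT-TN replicate 2 (207), and 783 without the expression filter. Calls lost with a library left out were those of Cmpk2 (adjusted p = 0.159 without WT-TN replicate 1, 0.0526 without WT-MP replicate 1, 0.167 without WT-TN replicate 2 and 0.052 without WT-MP replicate 2; voom 0.102) and Usp18 (0.0846 without WT-TN replicate 1, 0.141 without WT-TN replicate 2). Rab20 lost its call without mCre-TN replicate 1 (0.0911), and Cd86 without mCre-TN replicate 1 (0.0664) or WT-TN replicate 2 (0.0719).

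In MP cells, 498 genes differed, 256 higher and 242 lower in mCre, with 43 and 36 changed more than 2-fold. Slc6a13 rose from 641 ± 13 to 1430 ± 22 CPM (SD, n = 2 each; log2 fold change 1.16, SE 0.0505, adjusted p = 2.62e-11). Ptk2b fell by 1.22 (SE 0.0559, adjusted p = 4.44e-11), from 764 ± 12 to 328 ± 5.7 CPM. The fractalkine receptor gene Cx3cr1 rose from 8.49 ± 3.4 to 24.0 ± 0.78 CPM (1.501, SE 0.196, adjusted p = 0.000456). NK-type receptors fell: of 20 members, 12 were lower and 0 higher (16 and 1 adjusted over the list alone; median −0.69, camera adjusted p = 3.49e-27, kept with an estimated correlation at 0.00809). Among them the activating receptor gene Klrk1 fell by 0.49, from 185 ± 8.5 to 132 ± 2 CPM, and Klrc1 fell by 0.60. Klra7 (chromosome 6, 130218605 to 130233322, minus strand) fell by 3.11, from 14.9 ± 2 to 1.7 ± 0.15 CPM. Klra1 (−3.07) and Klra6 (−2.53) fell too, in a gene family whose reads cannot be assigned with certainty.

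The endosomal RNA sensor gene Tlr7 (1.47), Gadd45g (1.38), Isg20 (1.29), Cpm (1.245), Usp18 (1.13) and Rtp4 (1.11) also rose in mCre-MP. Zfp69 (−2.25), Syde1 (−1.01), the homing receptor gene Gpr15 (−0.94), Tcn2 (−0.92), Als2cl (−0.91), Ptprj (−0.89) and Camk2n1 (−0.86) fell. Interferon response genes rose in 20 of 38 cases and fell in 0 (32 and 0 adjusted over the list alone; median 0.75, camera adjusted p = 1.87e-48, but adjusted p = 0.132 with an estimated correlation). Irf9 (0.46), Trim30a (0.45) and Ddx58 (0.42) were among them. Of 13 co-inhibitory receptors, 3 rose and 0 fell (6 and 1 adjusted over the list alone; median 0.33, adjusted p = 0.00212, adjusted p = 0.298 with an estimated correlation): Lag3 (1.495), Tox (0.33) and Btla (0.31). Ribosomal protein genes fell in 5 of 83 cases (24 adjusted over the list alone; median −0.09, adjusted p = 9.08e-08, adjusted p = 0.848 with an estimated correlation). Of 16 myeloid markers, 2 fell (5 adjusted over the list alone; median −0.86, adjusted p = 0.000381, adjusted p = 0.575 with an estimated correlation), C1qa (−1.68) and Hmox1 (−1.12). The list did not pass without WT-MP replicate 1 (0.49) or mCre-MP replicate 1 (0.917). NK and innate lymphoid markers fell in 3 of 11 cases (3 adjusted over the list alone; median −0.28, adjusted p = 0.00841, adjusted p = 0.323 with an estimated correlation), Spry2 (−0.82), Xcl1 (−0.78) and Cd7 (−0.37). It did not pass without WT-MP replicate 2 (0.196) or mCre-MP replicate 1 (0.0657). Of 7 erythroid and platelet markers, 0 were called by edgeR, DESeq2 or voom, with 2 higher at an unadjusted p under 0.05 and 1 adjusted over the list alone. Their median was 0.71 (camera adjusted p = 0.0463, adjusted p = 0.575 with an estimated correlation). That list did not pass without WT-TN replicate 2 (0.0543), WT-MP replicate 2 (0.0602) or mCre-MP replicate 2 (0.53), or with the replicate number as a block (0.0776). Of 8 mitochondrially encoded genes, mt-Nd3 alone was called (−4.295, 172 counts in WT and 8 in mCre; list median −0.06, adjusted p = 0.0158, adjusted p = 0.298 with an estimated correlation, 0.103 without mCre-MP replicate 2).

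Calls in MP numbered 264 without WT-MP replicate 1, 308 without mCre-MP replicate 1, 195 without WT-MP replicate 2, 254 without mCre-MP replicate 2 and 888 without the expression filter. Lists that passed only with a library left out were naive T cell genes (6.85e-06), memory-phenotype markers (0.0407) and homing genes (0.0313) without mCre-MP replicate 1, and immediate-early (0.00551) and cell cycle genes (0.0324) without WT-MP replicate 1. Zfp69 lost its call when any library of WT-MP, mCre-TN or mCre-MP was left out (adjusted p = 0.0524 to 0.145; voom 0.0673). Camk2n1 lost its call without mCre-MP replicate 1 (0.0665), WT-MP replicate 2 (0.182) or mCre-MP replicate 2 (0.084) or with DESeq2 (0.0516). Usp18 did so without WT-MP replicate 2 (0.0779) or with the 2 MP groups alone (0.0536), and Ptprj without WT-MP replicate 2 (0.0514). The genotype differences in TN and MP shared 97 genes higher and 81 lower in mCre, where independent lists would share 4 and 4.6, and 4 genes were called in opposite directions. Across genes, which are not independent replicates, r was 0.438. Whether same-numbered TN and MP libraries came from one animal is not given in the labels, so this overlap and the comparison across subsets may rest on 2 animals per genotype. The shared calls numbered 108 without WT-MP replicate 1, 103 without WT-MP replicate 2, 107 without mCre-TN replicate 2 and 345 without the expression filter, against 178 in all.

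Across both subsets, with 4 libraries per genotype, 1358 genes were called, 623 higher and 735 lower in mCre, with 67 and 73 changed more than 2-fold. Slc6a13 (log2 fold change 1.248, SE 0.0405, adjusted p = 2.43e-15) and Ptk2b (−1.32, SE 0.0449, adjusted p = 1.11e-13, from 805 ± 64 to 323 ± 6.8 CPM, SD, n = 4 each) had small errors. Here and for Ly6a below, the SD is over TN and MP libraries together, so it includes any difference between the subsets. Type I interferon response genes rose in 32 of 38 cases and fell in 0 (35 and 0 adjusted over the list alone; median 0.75, camera adjusted p = 6.25e-56, but adjusted p = 0.0916 with an estimated correlation). Ifi27l2a (1.88), Oasl2 (1.65), Rsad2 (1.55), Ifit3 (1.54) and Ifit1 (1.32) were among them, as was Ly6a outside that list (2.17, SE 0.379, adjusted p = 0.0264; chromosome 15, 74994877 to 74998031), from 31.1 ± 18 to 144 ± 89 CPM. Myeloid markers fell beside this rise, in 8 of 16 cases (10 adjusted over the list alone; median −1.01, adjusted p = 2e-06, adjusted p = 0.808 with an estimated correlation). C1qa (−1.63), Slc40a1 (−1.28), Hmox1 (−1.22) and Vcam1 (−1.17) were among them.

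Other genes named across subsets were Gadd45g (1.29), Als2cl (−1.41), Arl4d (−0.76), Tcn2 (−0.76), Prss12 (−0.68), Unc5cl (−0.66), Igsf8 (−0.64) and Pam (−0.61). NK-type receptors fell in 12 of 20 cases (15 adjusted over the list alone; median −0.68, adjusted p = 3.69e-10, adjusted p = 0.693 with an estimated correlation). DESeq2 called 7 of the 20 lower and voom 14. In TN alone, 0 of the 20 were called by edgeR, DESeq2 or voom, and 5 were without a count in WT or in mCre. Whether the fall was confined to MP is not settled by this, since the interaction called 0 of the 20 members by edgeR, DESeq2 or voom. Ribosomal protein genes fell in 45 of 83 (60 adjusted over the list alone; median −0.12, adjusted p = 4.88e-15, adjusted p = 0.846 with an estimated correlation). With fry, the interferon list passed across subsets (adjusted p = 0.00786) and in MP (0.0293) but not in TN (0.0626). The NK-type receptors (0.153), myeloid markers (0.136) and ribosomal proteins (0.108) did not pass fry across subsets. The other lists were not called. Heat shock and unfolded protein genes moved both ways, 5 higher and 5 lower of 21 (7 and 6 adjusted over the list alone; adjusted p = 0.708). The chaperones Dnajb1 (−0.45), Hsph1 (−0.44) and Dnaja1 (−0.26) fell, and Asns (1.16), Ddit3 (0.26) and Xbp1 (0.24) rose. Cytotoxic effectors had 4 higher and 3 lower of 19 (adjusted p = 0.778). Gzmb (0.87) and Gzma (0.66) rose, and Xcl1 (−0.71) and Gzmm (−0.57) fell. Memory-phenotype markers (3 higher and 2 lower of 30, adjusted p = 0.674), naive T cell genes (3 and 2 of 30, 0.553) and cytokine receptors (6 and 2 of 26, 0.575) did not pass either. Nor did chemokine receptors and homing genes (5 and 2 of 24, 0.575), T cell receptor signalling (1 and 2 of 30, 0.53) and cell cycle genes (1 and 1 of 38, 0.778). The test was also missed by co-inhibitory receptors (4 and 1 of 13, 0.25, but 0.0209 without WT-TN replicate 1), DNA methylation genes (2 and 1 of 18, 0.25) and the microRNA pathway (1 and 0 of 14, 0.68). Erythroid and platelet markers had 2 of 7 higher (0.0954, but 0.00887 without the expression filter, 0.00698 without mCre-TN replicate 1 and 0.0214 without mCre-MP replicate 1). B cell markers had 0 of 9 called by edgeR, DESeq2 or voom and 0 at an unadjusted p under 0.05.

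Without WT-MP replicate 2, 855 genes were called across subsets. Several interferon-induced genes were close to the threshold: Ly6a lost its call when any WT or mCre-MP library was left out (adjusted p = 0.0643 to 0.1), and Ifit3 when any WT library or mCre-MP replicate 1 was (0.0698 to 0.0844). Leaving out any WT library ended the calls of Ifit1 (0.0589 to 0.0765) and Ifi27l2a (0.0504 to 0.0662), any WT or mCre-TN library that of Oasl2 (0.0505 to 0.0714), and WT-MP replicate 2 that of Rsad2 (0.0518).

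**Figure D3:**
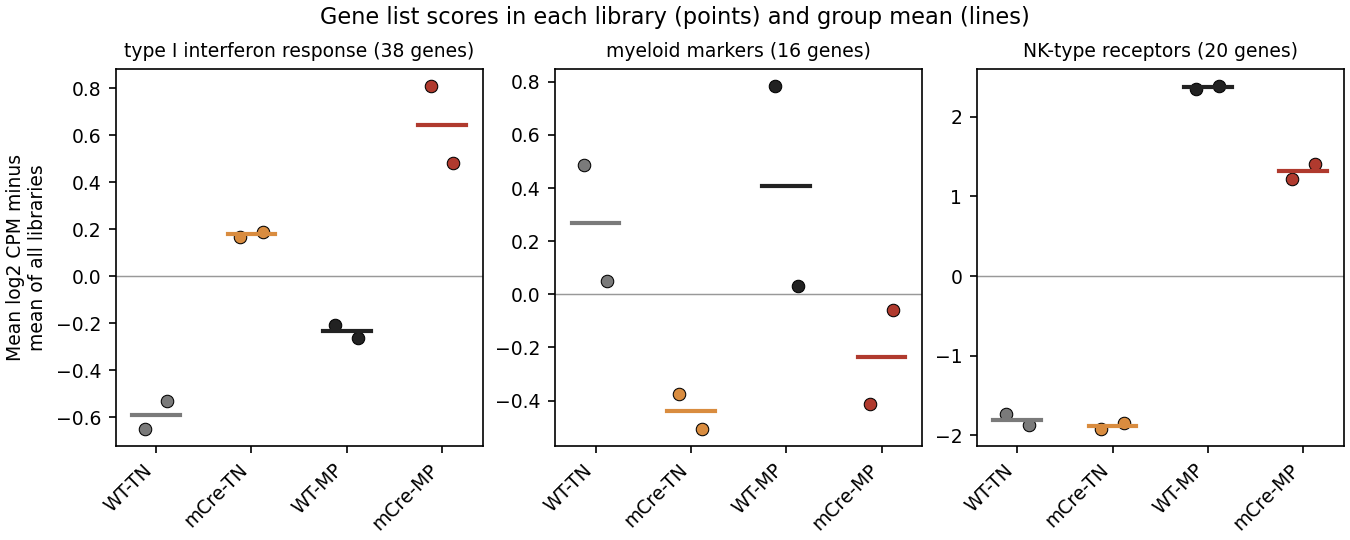
Mean log2 CPM of each gene list minus its mean over the 8 libraries (vertical axes, log2 scale) for 38 interferon response genes, 16 myeloid markers and 20 NK-type receptors. Points are libraries and lines are means of 2 libraries; both mCre libraries lie above both WT libraries of their subset for the interferon list, and the NK-type receptors are lower in mCre-MP than in WT-MP.

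Whether genes with miR-29 sites differed between the genotypes was asked next, since a loss of a microRNA would raise its targets on average. Of 29 tested published miR-29 targets, 2 rose across subsets, Lamc1 (1.22) and Tet2 (0.18), and 2 fell, Ppm1d (−0.22) and Klhdc3 (−0.15). Adjusted over the list alone there were 2 and 2, and the median was 0.002 (camera adjusted p = 0.778). DESeq2 called 0 higher and 2 lower, and voom 1 higher and 2 lower. Lamc1 was at a low level (mean log2 CPM −0.226) and close to the threshold (edgeR adjusted p = 0.04775). In TN, Klhdc3 alone was called (−0.24; list adjusted p = 0.691). In MP, 0 were called by edgeR, DESeq2 or voom, and 2 were higher and 3 lower at an unadjusted p under 0.05 (0.831). The subset difference of these targets was not called either, with 8 higher and 9 lower in WT (median −0.06 with an upward test, 0.206) and 9 higher and 13 lower in mCre (median −0.16 with an upward test, 0.416). Of the 29 targets, 24 carry the site TGGTGCT, which pairs to miR-29 positions 2 to 8, in the annotated 3' UTR.

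Over 11648 genes with an annotated 3' UTR, 1798 of them with TGGTGCT, the presence of the site went with a log2 difference of 0.0092 between mCre and WT across subsets (SE 0.0093, 95% interval −0.009 to 0.027). That was rank 1925 from the top among 15642 7mers (87.69 percentile). The estimate was 0.0074 in TN (SE 0.0119, interval −0.016 to 0.031, 71.97 percentile) and 0.0109 in MP (SE 0.011, interval −0.011 to 0.033, 86.84 percentile), and the site was called in none of these 3 comparisons. Genes are not independent replicates, so the rank describes these libraries. Camera on the 1798 site genes gave adjusted p = 0.492 across subsets, 0.354 in TN and 0.755 in MP. In simulation for each of the 3 comparisons, a shift of 0.1 of the genes with a site ranked first for 5 of 5 7mers tried, so a mean shift of that size would have been found. With 8mer or 7mer-A1 sites the estimate was −0.0019 in TN, 0.0157 in MP and −0.0022 across subsets, and it was not called. Among the 13 other microRNAs, genes with the miR-155 site AGCATTA were lower in mCre in TN (−0.0415, 0.28 percentile) and across subsets (−0.0302, 0.98 percentile), and those with the miR-21 site across subsets (2.19 percentile) and in MP (2.4 percentile). The miR-155 site in MP (3.36 percentile) and the miR-21 site in TN (8.13 percentile) did not pass. These were 4 of 39 such tests, where chance would give 1.95, and the comparisons share libraries.

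**Figure D4:**
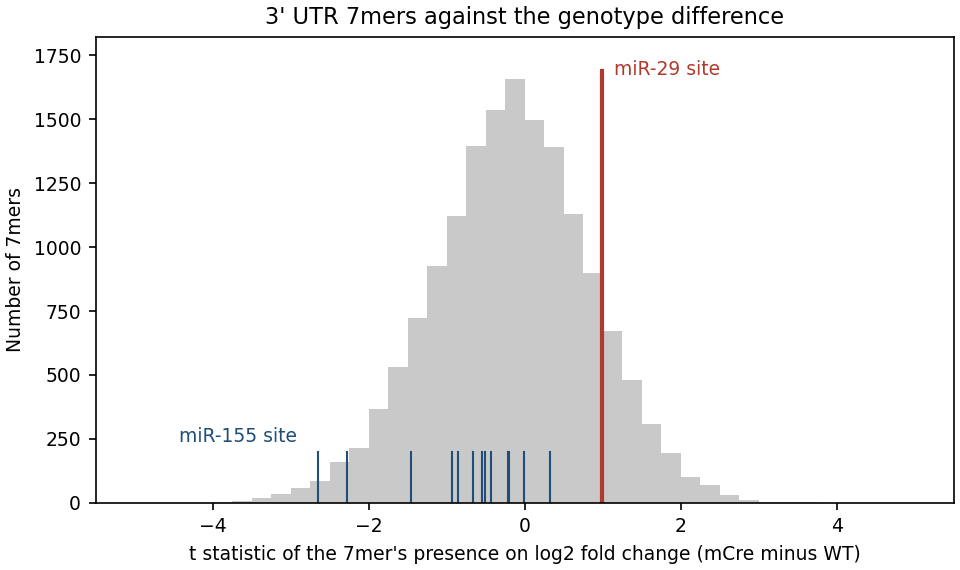
Distribution of the t statistic (horizontal axis) of each of 15642 7mers in 3' UTRs for the log2 fold change of mCre against WT across subsets; the vertical axis is the number of 7mers. The tall line is the miR-29 site at the 87.69 percentile, and the short lines are the sites of 13 other microRNAs, the leftmost that of miR-155 at the 0.98 percentile.

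Whether the subset difference itself differed between mCre and WT was tested with the interaction. The genotype difference ran in opposite directions in TN and MP for Ikzf2, which encodes the transcription factor Helios (chromosome 1, 69531214 to 69687245, minus strand). It was 0.57 in TN and −0.79 in MP, an interaction of −1.35 (SE 0.134, adjusted p = 3.75e-05). Mean CPM was 22.9 in WT-TN, 33.8 in mCre-TN, 29.1 in WT-MP and 16.8 in mCre-MP (n = 2 each). Cd86 (chromosome 16, 36603869 to 36666081, minus strand) was lower in mCre-TN (−0.79) and higher in mCre-MP (0.86), an interaction of 1.645 (SE 0.202, adjusted p = 0.00047). H2-Q6 (1.09), Traf1 (0.70), H2-Q7 (0.58) and Hopx (0.49) had positive interactions, and Edaradd (−1.44), the calcium-binding S100a6 (−1.16), Fam135b (−1.07) and Hectd2 (−1.03) negative ones. H2-Q6 and H2-Q7 are close paralogs whose reads may have been shared. In all, 16 genes were called, 6 positive and 10 negative, with 729 at an unadjusted p under 0.05.

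DESeq2 called 26 interactions, voom 7 and the fit without an expression filter 81, and the count was 9 without WT-MP replicate 1, 9 without WT-TN replicate 2, 10 without WT-MP replicate 2 and 32 without mCre-MP replicate 1. Hopx lost its call when any library other than mCre-TN replicate 2 or mCre-MP replicate 1 was left out (adjusted p = 0.062 to 0.176; voom 0.0914). Edaradd did so for any WT library or mCre-TN replicate 1 (0.0519 to 0.259; voom 0.0765), and Fam135b for any WT library, mCre-TN replicate 2 or mCre-MP replicate 2 (0.0796 to 0.21; voom 0.167, stricter filter 0.0517). S100a6 did not pass with voom (0.0633).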

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

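The interaction between genotype and subset was the planned test for results that differ between groups, and no test in this part was chosen only after its result was seen. The 16 genes called by edgeR are given with the interaction, (mCre minus WT in MP) minus (mCre minus WT in TN), on the log2 scale. Of these, 10 fall under the naming rule, and the other 6 are named because they were called. Voom called 7 interactions in all, so several of the 16 calls depend on the tool. The single-gene interaction calls named above as lost are all among the 10, and losses among the 6 are not given here. Gpr55, a lipid-sensing receptor gene, had the largest positive interaction of the 16 at 2.37 (adjusted p = 0.03), at levels of 0.621 to 8.51 CPM. Its genotype difference was −1.19 in TN, which was not called (adjusted p = 0.0895), and 1.18 in MP (adjusted p = 0.0045). Cd86 had 1.645, H2-Q6 1.086, Traf1 0.702, H2-Q7 0.58 and Hopx 0.491, the last 4 with a genotype difference close to 0 in MP (0.14, −0.09, 0.09 and −0.04) and a negative one in TN. Of the negative interactions, Il12rb2, a chain of the interleukin-12 receptor, had −1.636 (0.94 in TN, −0.69 in MP, adjusted p = 0.0252), Edaradd −1.44, Ikzf2 −1.354, S100a6 −1.164, Fam135b −1.071 and Hectd2 −1.028. Itm2a had −0.673 (adjusted p = 0.0252), Anxa2 −0.667 (0.03), Atf6 −0.587 (0.03) and Clec2i −0.483 (0.0448).

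Of the gene lists, 5 had an interaction past camera with the preset correlation, and each lost it with an estimated correlation. NK-type receptors had a median interaction of −0.395 (camera adjusted p = 0.0411; adjusted p = 0.4 with an estimated correlation), and co-inhibitory receptors 0.252 (0.000335; adjusted p = 0.262 with an estimated correlation). Glycolysis genes had 0.091 (0.0271), mitochondrially encoded genes −0.152 (0.0014) and ribosomal proteins 0.063 (0.0175), with adjusted p = 0.4, 0.262 and 0.857 with an estimated correlation. In each of the 5 lists, 0 members were called by edgeR; DESeq2 called 1 mitochondrial gene (lower) and 0 elsewhere, and voom 0. At an unadjusted p under 0.05, the counts higher and lower were 1 and 3 of 20 NK-type receptors, 4 and 0 of 13 co-inhibitory receptors, 1 and 0 of 21 glycolysis genes, 0 and 3 of 8 mitochondrial genes, and 3 and 1 of 83 ribosomal proteins. Other lists passed only with a library left out. Without WT-TN replicate 1 these were interferon (0.00961), gamma-delta (0.00961), transcription factor (0.0306) and miR-29 target genes (0.0306). Without WT-MP replicate 1 they were myeloid (0.000167), immediate-early (0.00645), cell cycle (0.0107) and naive genes (0.0377), and without mCre-MP replicate 1 naive (3.8e-07), myeloid (0.00629), homing (0.0339) and B cell genes (0.0388). The interferon list passed without mCre-TN replicate 2 (0.00304) or mCre-MP replicate 2 (1.62e-08), and the gamma-delta list without mCre-TN replicate 1 (5.58e-06), mCre-TN replicate 2 (0.000545) or mCre-MP replicate 2 (0.0217). The NK-type receptor interaction did not pass without mCre-TN replicate 1 (0.12), mCre-MP replicate 1 (0.126), WT-TN replicate 2 (0.267), WT-MP replicate 2 (0.167) or mCre-TN replicate 2 (0.164), nor with RLE size factors (0.0507), total counts only (0.0898) or no expression filter (0.0561). The glycolysis interaction did not pass with the stricter filter (0.0805), nor without WT-TN replicate 1, mCre-TN replicate 1, mCre-MP replicate 1 or WT-MP replicate 2. The ribosomal one did not pass without WT-TN replicate 2 (0.744, with the test turned down), WT-MP replicate 2 (0.232), mCre-TN replicate 2 (0.307) or mCre-MP replicate 2 (0.716).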

How the results depend on the processing

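The removal of single libraries, the other tools, scalings and filters, the replicate block and the fits of fewer groups were planned. Of 12061 single-gene values under these alternatives, 11444 (94.9%) kept their side of the threshold and, where called, their direction. Of the others, 428 were weaker, 189 were stronger and 0 reversed. These values and those of the lists include results that were not called, for which staying uncalled counts as kept. The shares therefore do not measure how stable the calls are. Of 2688 list values, 2521 (93.8%) stayed, 88 were weaker, 78 stronger and 1 reversed: the ribosomal protein list in the interaction, 0.01 without WT-TN replicate 2. With an estimated correlation 37 of 180 list results lost their call; with fry 17 lost and 19 gained it.

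Counts of calls that moved by more than 1.5 times with all libraries kept were those of the interaction with DESeq2 (26) and voom (7), and those without an expression filter: 783 for genotype in TN, 888 in MP, 81 for the interaction and 345 for the genes shared by the genotype comparisons. With 1 library left out, counts that moved as far were 204 and 207 for genotype in TN, 195, 254, 264 and 308 in MP, 855 across subsets, 9, 9, 10 and 32 for the interaction, and 103, 107 and 108 shared genes. More genes are tested without the filter; otherwise the cause was not tested. Leaving out each library in turn gave 2879 to 3836 calls for subset in WT, 2797 to 4187 for subset in mCre, 204 to 446 for genotype in TN, 195 to 593 in MP, 855 to 1198 across subsets and 9 to 32 for the interaction. The overlap ranged from 2302 to 2653 for the subset comparisons and from 103 to 180 for the genotype comparisons. The estimate for miR-29 sites ranged from 0.0033 to 0.0156 in TN, 0.0087 to 0.0191 in MP and 0.008 to 0.0164 across subsets. With 8mer or 7mer-A1 sites it was −0.0019, 0.0157 and −0.0022. The shortest UTR gave 0.0152, 0.0212 (95.93 percentile) and 0.0136. A model without covariates gave 0.0172, 0.0137 and 0.0167, and the stricter filter 0.0054, 0.0014 and 0.0035. The site was called under none of these. With a library left out each fit has fewer samples, so some loss of calls follows from the construction.

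Replicate numbers are shared between groups, but nothing in the labels says that they pair samples. Deviations from the group means correlated at 0.11 between same-numbered WT-TN and WT-MP libraries, at 0.077 between mCre-TN and mCre-MP, and at −0.045 to −0.014 for the other pairings. With the replicate number as a block, 4036 genes were called for subset in WT, 4145 for subset in mCre, 548 for genotype in TN, 617 in MP, 18 for the interaction and 1446 across subsets, with overlaps of 3046 and 240. This block gave WT and mCre libraries of the same number a shared effect, whereas the positive correlations lay within a genotype. It therefore does not model TN and MP libraries from a single animal. The share of higher calls moved by less than 10 percentage points under each scaling, at most from 44.7% to 54.1% for genotype in TN with total counts. It moved further toward higher calls for genotype in TN without mCre-TN replicate 1 and for genotype in MP without mCre-MP replicate 2. For the interaction, 6 of 16 calls were positive with edgeR, 13 of 26 with DESeq2 and 4 of 7 with voom. Positive interaction calls outnumbered negative ones without mCre-MP replicate 1 or WT-TN replicate 2, among others. The balance of signs in the interaction therefore depends on the tool and the libraries. Depth limits the genes of few counts, such as the miR-29 precursors and Cd4. The shallowest library was WT-TN replicate 1, at 13479586 counts; without it 348 genes were called for genotype in TN.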

Other observations

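The test over other splits of the libraries was planned, and its limit to splits with 2 libraries of each subset on either side was set after its result had been seen. The tests of the 3 patterns and of the amino-acid genes below, and the lists of macrophage and amino-acid genes they used, were chosen only after the results they bear on had been seen. So were the genes named here outside the naming rule, after their values had been seen.

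Genes of amino-acid supply were higher in mCre across subsets. Of 20 cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, 11 rose and 0 fell (13 and 0 adjusted over the list alone; median 0.13, camera adjusted p = 0.0308 with an estimated correlation). Cars (0.59) and Aars (0.45) were among them. Of 18 tested genes of amino-acid transport, synthesis and the stress response to their lack, 8 rose and 1 fell (9 and 1 adjusted over the list alone; median 0.17, adjusted p = 0.0293 with an estimated correlation). Asns (1.16), Slc1a4 (1.59), Slc7a5 (0.57) and Mthfd2 (0.53) rose and Cebpg (−0.20) fell. The lists were drawn up after 6 of these genes had been noticed, and their p-values were not adjusted together with the fixed lists. A joint response of both groups may underlie this. The 32 tested members that had not been seen gave 13 higher and 1 lower, a median of 0.10 and an adjusted p of 0.0419 with an estimated correlation. Within a single subset that p was 0.102 in TN and 0.0724 in MP.

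Some genes fell steeply in mCre. The mitochondrial gene mt-Nd3 fell by 4.34 across subsets (adjusted p = 6.31e-09), while the list it belongs to was not called. Mical3 (−2.84), the innate-like T cell factor Zbtb16 (−2.61), Scn2b (−5.14), Capn11 (−4.48) and Slc35e4 (−3.09) fell as well. Their mean log2 CPM was 1.36, −0.691, 2.447, 3.376 and 1.821 in that order, so Zbtb16 was close to the floor. Gm26825 fell by 4.82 (chromosome 5, 5781530 to 5783636), with Gm15459 antisense to it. Rag1, a recombinase gene (chromosome 2, 101638282 to 101649501), and Agtr1a had 0 counts in each mCre library, and were low in WT as well (1.427 and 1.33 CPM in TN, 0.489 and 0.3698 CPM in MP). Slc6a12, next to Slc6a13, rose by 1.56. The heme synthesis gene Alas2 (0.91) and the globin gene Hba-a1 (0.605) rose.

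The planned test took the 34 splits of the 8 libraries into 4 and 4 that keep a fit with subset as covariate. The real split alone, 1 of 34, gave as many genotype calls across subsets, 1358 against 8 for the highest of the others, which is under the share of 0.05 named in advance. Only 18 of these splits hold 2 libraries of each subset on either side and can stand for the real one. Among them it was 1 of 18, and 18 splits are too few for a share under 0.05.

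Of 38 interferon response genes, 13 were called higher in mCre in TN and 20 in MP (25 and 29 with DESeq2, 9 and 17 with voom), and the list was not called with an estimated correlation (adjusted p = 0.378 and 0.132). RNA of myeloid cells, which express many of these genes, would need raised myeloid markers, and the median of the 16 tested myeloid markers was −1.011, with 8 called lower. Another strain background cannot be told apart from the genotype: the 32 members called across subsets lie on 14 chromosomes, but with 32 of 38 called the list itself sets that number. An exposure, a cage or a day shared by the mCre animals could also raise the list, and no label gives cage or day. All 4 of the 4 mCre libraries scored above both WT libraries of their subset. That restates the rise and cannot separate such a cause from the genotype. The genotype itself stays open as an untested explanation.

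Myeloid markers that fell in mCre included genes of red-pulp macrophages, which clear red cells in the spleen and which the sort for CD8 should remove. Less macrophage RNA in the mCre libraries is a candidate explanation. The 11 tested macrophage genes outside the myeloid list had a median of −1.102, with 90.9% of them lower and 8 called lower, and camera gave adjusted p = 4.73e-07, and adjusted p = 0.0569 with an estimated correlation. Their mean log2 CPM minus the mean over the 8 libraries was 0.694 and 0.765 in replicate 1 of WT-TN and WT-MP, 0.334 and 0.056 in replicate 2, and −0.616 to −0.351 in mCre; without WT-MP replicate 1 the median was −0.876, with 3 called lower. Less RNA of every other cell type was also considered. The highest of the medians of B cell (−0.17), dendritic (0.09) and erythroid markers was 0.707, with 2 of 7 erythroid members called higher. This test was chosen after these values had been seen, so its outcome was known and it decides nothing. The erythroid list was not called (camera adjusted p = 0.0954, and 0.846 with an estimated correlation), and its score was 0.726 and 0.566 in mCre replicate 2, 0.026 and −0.115 in mCre replicate 1 and −0.584 to −0.095 in WT (TN before MP). Whether the macrophage RNA differed through the sort, the spleens or the genotype was not tested.

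Genes changed more than 2-fold between genotypes lay near each other in places, such as Mical3, Usp18, Slc6a13 and Slc6a12 on chromosome 6, which could point to segments of another genetic background around an allele bred into the mCre line. Of 139 such genes, 33 had another within 1 Mb, against a median of 29 and an upper limit of 42 in 10000 expression-matched draws (permutation p = 0.288). Without listed genes, and with only neighbours of another symbol stem (the symbol up to its first digit or hyphen) counted, 13 of 102 did. The median of the draws was 16 (permutation p = 0.744), and this count leaves out called genes and so excludes nothing. The highest number in a 10 Mb window, each symbol stem counted once, was 6, on chromosome 6 from 120000001 to 130000000. The draws had a median of 5 and an upper limit of 7 (permutation p = 0.163). Klra5 and Klre1, both NK-type receptor genes, counted as separate stems in that window. With each gene counted, the window from 125000001 to 135000000 on that chromosome held 9 of 73 tested genes, all lower Klra and Klre1 genes of the NK-type receptors whose reads may have been shared. The 33 and the 6 lie above the middle of their draws without passing, so segments cannot be told apart from chance neighbours with these counts. Within 5 Mb of Mir29a, 1 of 46 tested genes had such a change and near Mir29c 0 of 31, against 139 of 12299 over the genome (1.13%; Fisher's exact test, two-sided, p = 0.408 and 1).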
